A study of Drosophila melanogaster with 35 samples.

How the data were processed

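The samples are 35 poly(A) RNA libraries of adult female flies, 17 of fat body and 18 of gut, in 2 genotypes with and without RU486 feeding. Per the labels, flies were dissected, RNA was extracted with Trizol and chloroform, and libraries were made with a directional kit that carries molecular barcodes. The deposited tables hold raw read counts per gene, and the submitters' processing notes name FastQC, HISAT2, SAMtools, featureCounts and DESeq2. The tool versions, genome build, annotation, strand setting and any use of the molecular barcodes are not given in the sources used here. Without such use, PCR copies would be counted as separate reads. The treatment label names RU486 for every sample while the induction label names none for the control groups; the induction label and titles set the groups.

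The fat body table holds 14649 rows, of which 14538 matched a gene symbol, and the gut set 14344 rows. Counts per library ran from 6708078 to 27527703 in the fat body and from 4509476 to 16976256 in the gut. Of the fat body rows with a mean of at least 10 counts, 189 of 9652 held counts identical to another row in each library, and 177 of 9383 in the gut. Overlapping and antisense genes are therefore uncertain. Coordinates are those of the BDGP6 Ensembl annotation in the reference used here, which need not be the authors' build.

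From the deposited counts, edgeR 4.0.16 (R 4.3.3) fitted the 4 groups of a tissue together. Genes with low counts were removed by filterByExpr, library sizes were scaled by TMM, and the robust quasi-likelihood test was run with Benjamini-Hochberg adjustment at 0.05. This tested 9819 fat body genes and 9705 gut rows, which held 99.92 percent of the counts in each tissue. The common biological coefficient of variation was 0.510 in the fat body and 0.354 in the gut. Fold changes are on the log2 scale with the quasi-likelihood SE, and CPM values are scaled by TMM. Per-library log2 CPM used a prior count of 2.

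Lists of pathways, complexes and cell type markers were fixed before the data were examined, with the groups, the tests and the rule for named genes. The 39 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. One list alias that led to an unrelated splicing gene was removed. The difference of the switch effect between the tissues, planned as a joint fit, was not tested because the gut identifiers did not go with the counts. The named genes are foxo, Xbp1, Thor and InR, the genes past the threshold where fewer than 5 passed, and up to 4 members of smallest adjusted p from each list past the threshold.

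Alternatives fixed in advance were RLE size factors, DESeq2 1.42.0, limma-voom with limma 3.58.1, other filters, a fit on the compared groups alone, blocks for the title replicate number and for the library round, 1 surrogate variable with sva 3.50.0, a threshold of 0.01, and leaving out each library. Chosen after the data were seen were 2 and 3 surrogate variables, the ovary and egg mean, the cell cycle mean, both means, the cell cycle mean with the round block, removal of a trend on exon length, a fit without libraries high in ovarian transcripts, added group contrasts, relations centred within library rounds, gene list tests with each library left out, and splits that part paired libraries. Exon length was known for 99.2 percent of tested fat body genes.

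Library rounds were set from the library numbers in the labels. Libraries with the same title number correlated in their deviations from the group means at 0.412 to 0.840 for the gut S106 groups and at 0.175 to 0.771 for the gut control groups, so these numbers were taken to pair the libraries. For the gut S106>UASfoxo groups the title numbers gave −0.582 to −0.286 and the library rounds 0.352 to 0.625, so the rounds were taken to pair them. Fat body title numbers gave −0.420 to 0.770 for the S106 groups, −0.518 to 0.737 for the control groups and −0.063 to 0.584 for the S106>UASfoxo groups, so they were not taken to pair. The fat body library rounds gave −0.420 to 0.770 for the S106 groups, −0.169 to 0.584 for the S106>UASfoxo groups and 0.406 to 0.737 for the control groups, so there the rounds were taken to pair the control groups alone.

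The tests were run on simulated data with the real means, library sizes and dispersions, with 200 genes changed. For the fat body S106>UASfoxo switch comparison, over 9819 genes, edgeR recovered 13.4 percent of genes changed by a log2 fold of 1, 55.2 percent at 2 and 81.8 percent at 3, and called 4 unchanged genes, where DESeq2 called 30 and limma-voom 3. DESeq2 recovered 29.9, 70.1 and 90.9 percent of the changed genes at these folds. For the same comparison in the gut, over 9705 rows, edgeR recovered 43.3, 77.6 and 89.4 percent. A simulated shift of the glycolysis list was called by camera with either correlation. The simulated genes were drawn independently, while the real glycolysis genes had an estimated correlation of 0.804 in this fat body comparison. The simulation therefore does not show whether camera with an estimated correlation could call such a shift in the real data.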

Results

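Poly(A) RNA was sequenced from the fat body and gut of female Drosophila melanogaster aged 30 days. The fat body is the fly tissue of nutrient storage and intermediary metabolism. S106 is a GeneSwitch driver, which activates a UAS transgene when the flies eat the steroid RU486. S106>UASfoxo flies also carry a UAS transgene for dFOXO, the forkhead transcription factor of insulin signalling. The switch groups ate 200 µM RU486 for 21 days and then control food for 7 days, and the control groups are labelled as without RU486. The fat body set held 5 S106 control, 4 S106 switch, 4 S106>UASfoxo control and 4 S106>UASfoxo switch libraries, with total counts of 6708078 to 27527703. The gut set held 4 S106 control, 5 S106 switch, 5 S106>UASfoxo control and 4 S106>UASfoxo switch libraries, with total counts of 4509476 to 16976256. The labels do not say whether libraries of a group came from separate fly cultures, so the p-values measure only the spread between these libraries.

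The comparison of S106>UASfoxo switch with S106>UASfoxo control asks what remains in the tissue a week after dFOXO overexpression ends. In the fat body, lists of sugar and lipid metabolism had positive median log2 fold changes, but no single gene passed edgeR's test. Ovary and egg markers had a median of 1.13, with 19 of 28 higher, and spermatheca markers 1.025, with all 6 higher. Neither marker list passed camera, with adjusted p-values of 0.468 and 0.0796. With the library round as a block both passed camera, with 0.0102 and 0.0349. The 14 glycolysis genes were all higher, with a median log2 fold change of 1.18. Among them, enolase (Eno) had a log2 fold change of 1.46 ± 0.44 (SE), phosphoglycerate kinase (Pgk) 1.49 ± 0.45 and phosphoglycerate mutase (Pglym78) 1.22 ± 0.36, with n = 4 libraries in each group. Adjusted over the list alone, 8 glycolysis genes passed; adjusted over all genes tested, 0 did by edgeR. Over the list alone none passed without S106>UASfoxo control replicate 4, S106>UASfoxo switch replicate 1 or S106>UASfoxo switch replicate 2. Pyruvate carboxylase (PCB) and Pepck1, which feed gluconeogenesis, had log2 fold changes of 1.88 ± 0.72 and 1.64 ± 0.66, in a list of 11 genes with a median of 0.70.

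Lipid genes had positive medians in both directions of metabolism. The lipid synthesis list had a median of 0.62, with 15 of 22 members higher. Its members FASN2, a fatty acid synthase, and Pgd, an enzyme of the pentose phosphate pathway, had log2 fold changes of 1.86 ± 0.74 and 1.62 ± 0.68. The lipid breakdown list had a median of 0.47, with 14 of 16 members higher. Mtpbeta, of the mitochondrial trifunctional protein, stood at 1.76 ± 0.59, and the acyl-CoA dehydrogenase Mcad at 1.40 ± 0.57. The hemocyte marker list had a median of 0.63, and its members of smallest adjusted p, vkg at 2.41 ± 0.72 and Col4a1 at 2.26 ± 0.71, encode type IV collagen of basement membranes. Mitochondrial ribosomal protein genes had a median of −0.36, with 65 of 72 members lower, mRpL18 at −0.62 ± 0.23 among them. Glutathione S-transferases had a median of −0.26, with GstZ1 at −0.91 ± 0.31. Without S106>UASfoxo control replicate 4 the mitochondrial ribosomal median was −0.17, and the list still passed camera with the preset correlation. Without S106>UASfoxo switch replicate 3 the glutathione S-transferase list did not, with a camera adjusted p of 0.0659. Without S106>UASfoxo control replicate 4 the lipid synthesis, lipid breakdown and gluconeogenesis lists did not pass camera, with medians of 0.34, 0.19 and 0.39. The glycolysis list did at the preset correlation, with 0.87. At an estimated correlation, with all libraries, the glycolysis list had a camera adjusted p of 0.994.

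Digestive enzyme genes, which are abundant in gut enterocytes, had positive medians in the fat body, with no member passing over all genes tested by edgeR, while DESeq2 called Amy-p. The carbohydrase and lipase list had a median of 2.08, with the amylase Amy-p at 3.67 ± 1.03, and the digestive protease list a median of 1.09, with epsilonTry at 3.44 ± 1.18. Amylase and trypsin genes have near-identical copies, so their single values are uncertain. Both lists rested on S106>UASfoxo switch replicate 2, where the protease list mean was 4.10 log2 CPM against 0.01 to 2.34 in the rest of its group. Without that library their medians were 0.51 and 0.05, with camera adjusted p-values of 0.324 and 0.892. The enterocyte marker list, which shares members with both, had a median of 1.09 and did not pass, with a camera adjusted p of 0.0978. Apart from that list, these 9 lists passed camera with a preset correlation. With the library round as a block the carbohydrase and protease lists did not pass, with camera adjusted p-values of 0.357 and 0.408. With an estimated correlation each of the 9 had an adjusted p = 0.994, and fry called 0 of the 39 lists. Of the 35 splits of these 8 libraries into groups of 4, 31 gave at least as many lists. The log2 fold changes also followed exon length across genes, with a Spearman rho of 0.377 over 9739 genes, which are not independent replicates.

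**Figure D1:**
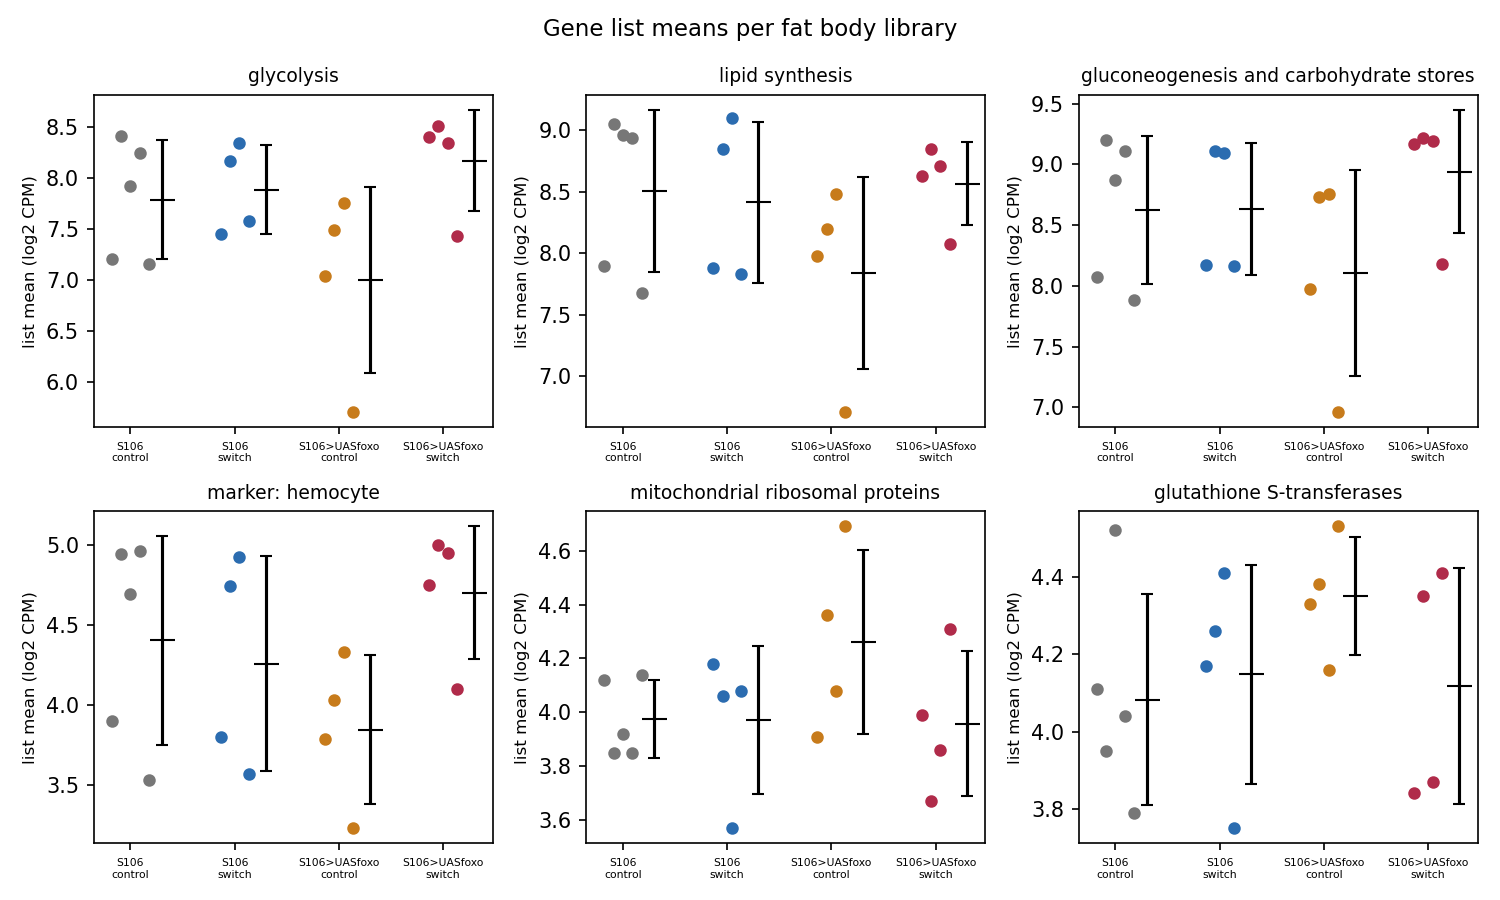
Mean log2 CPM of 6 gene lists in each fat body library; each point is 1 library, and the black mark and bar give the group mean and SD. For glycolysis the S106>UASfoxo control mean was 7.00 ± 0.91 and the S106>UASfoxo switch mean 8.17 ± 0.50, with S106 control at 7.79 ± 0.58 between them.

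The 4 genes fixed in advance did not pass in this comparison. The foxo gene itself, FBgn0038197 at 3R from 14056945 to 14087978, averaged 163 CPM in S106>UASfoxo switch and 105 CPM in S106>UASfoxo control, a log2 fold change of 0.63 ± 0.35 with an edgeR adjusted p of 0.457. Xbp1, a transcription factor of the endoplasmic reticulum stress response, had a log2 fold change of 1.43 ± 0.58 with an edgeR adjusted p of 0.320. Thor, the translation inhibitor 4E-BP, stood at −0.01 ± 0.52, and the insulin receptor gene InR at −0.37 ± 0.45. The direction of Thor turned without S106>UASfoxo control replicate 3, at 0.18, and without S106>UASfoxo switch replicate 1, at 0.17, and that of InR without S106>UASfoxo control replicate 3, at 0.08. The textbook dFOXO target list had a median of 0.10 over 21 genes and neither this list nor the 34 genes of protein folding in the endoplasmic reticulum passed, with camera adjusted p-values of 0.530 and 0.983.

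Across all 9819 genes tested, edgeR's quasi-likelihood test called 0 genes at an adjusted p under 0.05 and limma-voom 0, while DESeq2 called 53, of which 41 were higher in the switch group. In simulated data of this comparison with 200 changed genes, DESeq2 called 30 unchanged genes and edgeR 4. DESeq2 also recovered more of the changed genes, 29.9, 70.1 and 90.9 percent at log2 folds of 1, 2 and 3, against 13.4, 55.2 and 81.8 for edgeR. The 30 therefore do not say how many of the 53 are false. At an unadjusted p under 0.05 edgeR gave 1269 genes, 992 of them higher, where chance gives 491. Here and below the number of chance is 0.05 of the genes or rows tested. Over other splits of the same libraries the median was 224. The glycolysis mean of S106>UASfoxo control was the lowest of the 4 groups, and leaving out replicate 4 of that group brought the 1269 genes to 670. Leaving out S106>UASfoxo switch replicate 1 brought them to 812, and leaving out S106>UASfoxo control replicate 3 raised them to 1716. With title and round blocks the 1269 became 1805 and 1790. In fits chosen after the data were seen, the mean of the ovary and egg marker list as a covariate gave 1480 called genes, and the mean of the cell cycle list gave 1.

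In flies with the driver alone, S106 switch against S106 control measures what RU486 feeding leaves behind without the transgene. The widest fitted difference among named fat body genes was that of Cp38, a chorion protein of the eggshell, with a log2 fold change of 6.93 ± 2.12 and an edgeR adjusted p of 1.00. It rested on S106 switch replicate 4: without that library the value was −0.93. The ovary and egg list had a median of 0.71, with 27 of 28 members higher, and all 33 cell cycle genes were higher, with a median of 0.56. Both lists rested on the same library: without S106 switch replicate 4 their medians were −0.02 and −0.09, with 13 and 7 members higher, and neither passed camera. Chromatin remodeller genes had a median of 0.25, with 34 of 36 higher, and histone modifier genes 0.18, which became −0.05 and −0.08 without that library. Muscle markers had a median of −0.34, with all 17 lower, and antimicrobial peptides −0.37. Without S106 switch replicate 4 the muscle median was −0.11, with a camera adjusted p of 0.150. Without S106 control replicate 3 the antimicrobial peptide median was −0.195, with a camera adjusted p of 0.682. That list did not pass in 5 of 9 fits with a library left out. Neuron, oenocyte, respiratory chain and cytosolic ribosomal protein lists had medians of −0.11, −0.20, −0.15 and −0.11. With single libraries left out these 4 lists did not pass camera in 5, 3, 5 and 5 of 9 fits. Camera's direction turned in 1 of those fits for the respiratory chain and in 3 for cytosolic ribosomal proteins. These 10 lists passed camera with the preset correlation, 4 lists passed without S106 switch replicate 4 and 19 without S106 switch replicate 3, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.955. With the library round as a block the neuron list did not pass, with a camera adjusted p of 0.0957. foxo stood at −0.08 ± 0.33, Xbp1 at 0.10 ± 0.54, Thor at −0.20 ± 0.49 and InR at −0.52 ± 0.43. With single libraries left out, foxo ran from −0.23 to 0.13, Xbp1 from −0.23 to 0.33 and Thor from −0.53 to 0.05. edgeR and limma-voom called 0 genes and DESeq2 called 1. Against 491 by chance and a median of 142 over other splits, 68 genes had an unadjusted p under 0.05. That number ran from 28 without S106 switch replicate 4 to 185 without S106 control replicate 5. It was 45 and 38 without S106 control replicates 3 and 4, 153 and 136 without S106 switch replicates 2 and 3, and 598 with the title replicate block.

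Ovarian transcripts varied widely between fat body libraries of every group. The ovary and egg list mean ran from −1.31 log2 CPM in S106>UASfoxo control replicate 2 to 6.58 in S106 switch replicate 4. The cell cycle list mean ran from 0.39 to 6.44 over the same 17 libraries. The means of both lists went together, with a Pearson r of 0.895 and a Spearman rho of 0.900, each with a permutation p of 1e-05, the smallest the permutations can give. Their Benjamini-Hochberg adjusted values over the 2 relations tested were 2e-05. Without the 2 libraries farthest from the median, r was 0.879. With both means centred within the 5 library rounds, r was 0.845 and rho 0.811, with permutation p-values within rounds of 0.001 and 0.004, or 0.002 and 0.008 adjusted over the 2 relations. Without the 2 farthest libraries the centred r was 0.747. The rounds held 51 percent of the variance of the ovary and egg mean, where chance gives 25 percent, with a permutation p of 0.06.

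**Figure D2:**
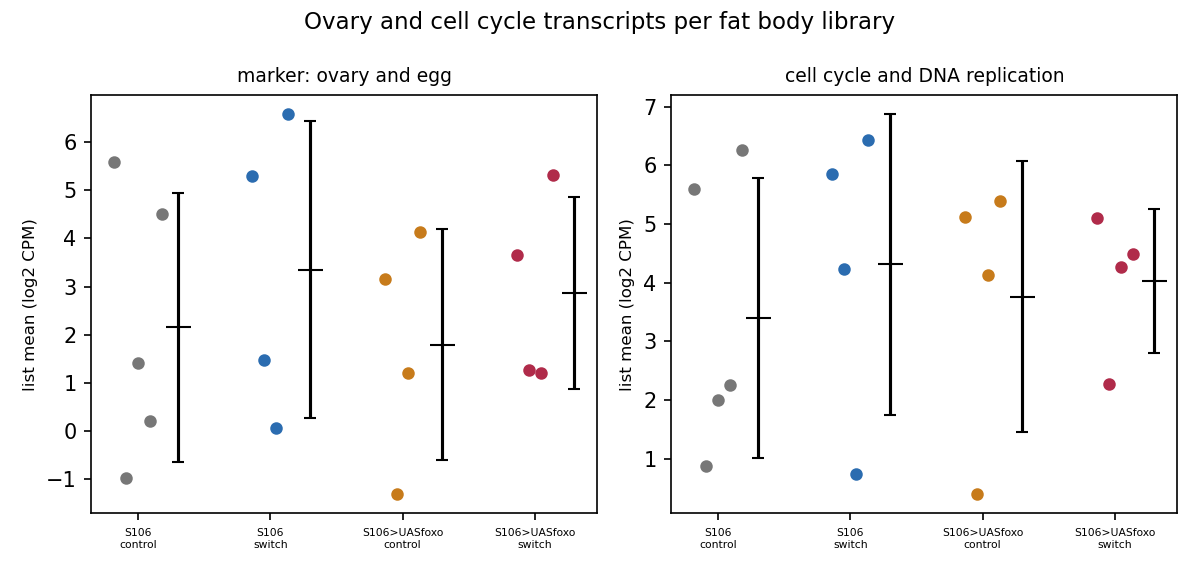
Mean log2 CPM of the ovary and egg markers and of the cell cycle genes in each fat body library; each point is 1 library, and the black mark and bar give the group mean and SD. Within each group the ovary and egg values spread over several log2 units, from −1.31 to 6.58 across the 17 libraries.

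The difference of the 2 switch effects tests whether the response to RU486 depends on the transgene. Glycolysis genes of the fat body had a median difference of 1.02, lipid synthesis genes 0.78 and hemocyte markers 1.03, and mitochondrial ribosomal protein genes −0.34. Single members were Ldh, lactate dehydrogenase, at 1.64 ± 0.76, the long-chain acyl-CoA synthetase bgm at 1.42 ± 0.57 and vkg at 2.16 ± 0.96. Digestive proteases had a median of 2.37, which became 0.64 without S106 switch replicate 4, 0.69 without S106>UASfoxo switch replicate 2 and 1.14 without S106 control replicate 4. Their mean in that S106 control library was 4.45 log2 CPM, against 0.88 to 2.41 in the rest of its group. Muscle markers had a median of 0.55, with the myosin heavy chain gene Mhc at 1.62 ± 0.68. Of 39 lists 16 passed camera with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.709. The 16 became 5 without S106 switch replicate 4, 8 without S106>UASfoxo switch replicate 2 and 23 without S106 switch replicate 3. No gene passed: edgeR, DESeq2 and limma-voom each called 0, and the smallest edgeR adjusted p was 0.950. At an unadjusted p under 0.05 there were 185 genes, where chance gives 491 and other splits a median of 202. Single libraries moved the 185 to either side of chance: it was 81, 98 and 411 without S106 control replicates 4, 2 and 5, and 86 and 553 without S106 switch replicates 1 and 3. Without S106>UASfoxo control replicates 3 and 4 it was 520 and 95, without S106>UASfoxo switch replicates 2, 3 and 4 it was 113, 114 and 514, and with title and round blocks 1171 and 907. With the round block 11 lists passed, and cell cycle genes, neuron markers, enterocyte markers and both digestive lists did not, with camera adjusted p-values of 0.489, 0.139, 0.293, 0.394 for carbohydrases and 0.189 for proteases. foxo stood at 0.71 ± 0.48, Xbp1 at 1.33 ± 0.79, Thor at 0.19 ± 0.71 and InR at 0.15 ± 0.62. With single libraries left out, Thor ran from −0.06 to 0.53 and InR from −0.19 to 0.60.

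S106>UASfoxo control against S106 control gives the genotype difference without inducer. There 3 fat body genes were higher in S106>UASfoxo and 1 was lower, and edgeR gave each an adjusted p of 0.0438. dpr9, a cell surface protein of the immunoglobulin superfamily (FBgn0038282, 3R from 15054930 to 15077206), averaged 8.00 ± 4.89 CPM (SD, n = 4) against 0.431 ± 0.311 CPM (SD, n = 5), a log2 fold change of 4.20 ± 0.65. Dop1R1, a dopamine receptor (FBgn0011582, 3R from 14165379 to 14214810), averaged 9.12 ± 2.09 CPM against 0.811 ± 0.543 CPM, a log2 fold change of 3.52 ± 0.57. Argp (FBgn0051469, 3R from 13709159 to 13709939) had a log2 fold change of 3.10 ± 0.50. CG43064 (FBgn0262366, 3L from 11834721 to 11836721) averaged 4.57 ± 1.85 CPM against 17.3 ± 4.42 CPM, a log2 fold change of −1.92 ± 0.32. All 4 kept their direction in every alternative fit tried. With the library round as a block edgeR called 2 genes, both higher, with dpr9 and Dop1R1 past the threshold and Argp and CG43064 not. Leaving out any single library of the compared groups gave 0 or 1 called genes. The 1083 genes at an unadjusted p under 0.05 became 493, near the 491 of chance, without S106>UASfoxo control replicate 4, and 711 without S106 control replicate 2. With title and round blocks they became 1667 and 1650. Other splits of all libraries of these groups gave a median of 177. Nearness to 491 alone therefore does not say that no difference remained. DESeq2 called 18 genes and limma-voom 2. In simulated data of this comparison with 200 changed genes, edgeR called 5 unchanged genes, DESeq2 28 and limma-voom 6. DESeq2 recovered 35.8, 76.1 and 93.9 percent of genes changed by log2 folds of 1, 2 and 3, and edgeR 16.4, 62.7 and 84.8.

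**Figure D3:**
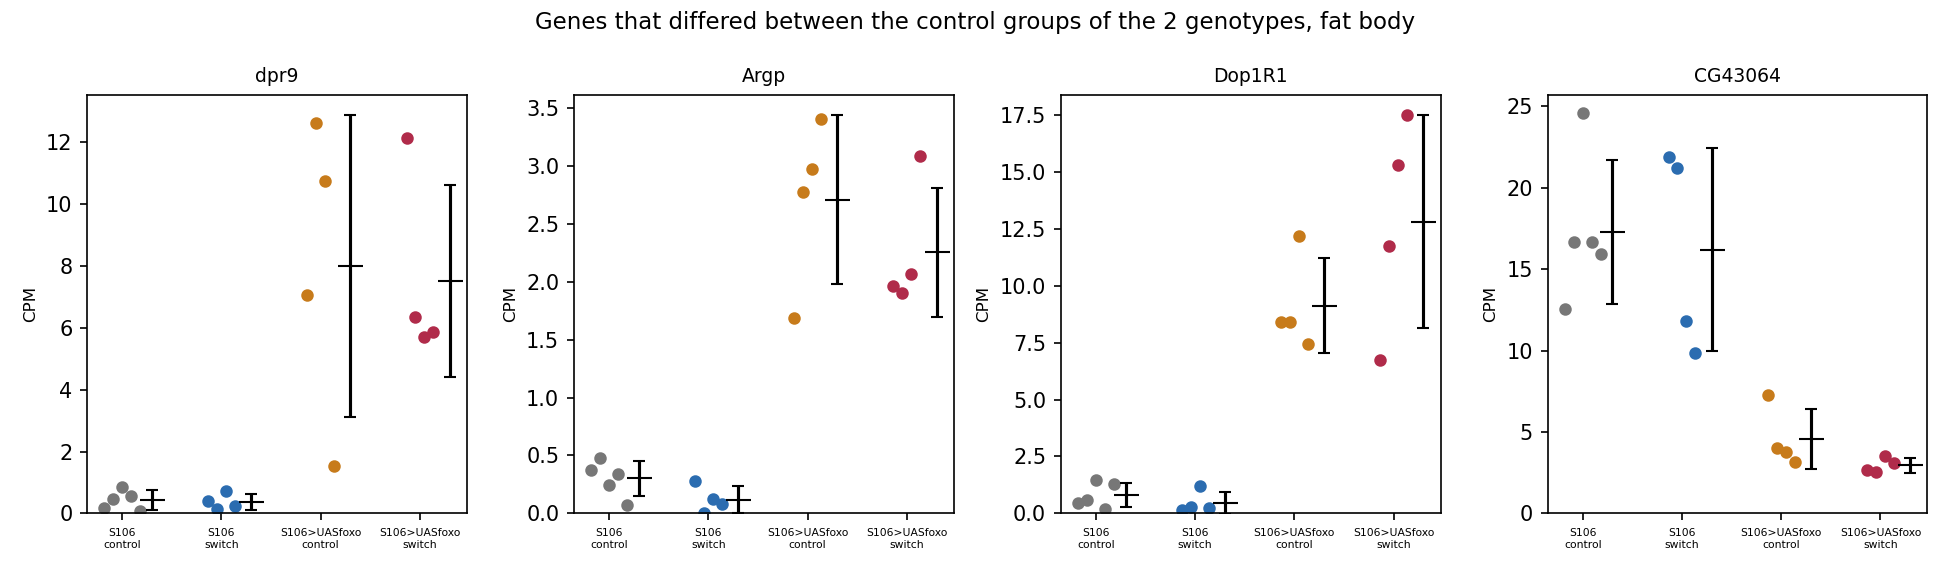
CPM of dpr9, Argp, Dop1R1 and CG43064 in each fat body library; each point is 1 library, and the black mark and bar give the group mean and SD. Dop1R1 averaged 9.12 and 12.8 CPM in the S106>UASfoxo groups and 0.811 and 0.470 CPM in the S106 groups.

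Lists of sugar and lipid metabolism had negative medians in S106>UASfoxo control against S106 control, with no member passing over all genes tested by edgeR. Glycolysis genes had a median log2 fold change of −0.76, with all 14 lower, Pgk at −1.15 ± 0.43 and Eno at −1.02 ± 0.42. Without S106>UASfoxo control replicate 4 the glycolysis median was −0.48, with a camera adjusted p of 0.0139 at the preset correlation. Lipid synthesis genes had a median of −0.61, with FASN1, a fatty acid synthase, at −1.25 ± 0.54, and lipid breakdown genes −0.36, with Mtpbeta at −1.48 ± 0.57. Without S106>UASfoxo control replicate 4 neither lipid list passed camera, with medians of −0.50 and −0.14. Digestive proteases and spermatheca markers had medians of −1.67 and −1.30, and with the library round as a block the protease list did not pass, with a camera adjusted p of 0.342. Without S106 control replicate 4 the protease median was −0.33, with a camera adjusted p of 0.271. With single libraries left out the protease list did not pass camera in 3 of 9 fits. Its highest camera adjusted p was 0.886, without S106>UASfoxo control replicate 3. The spermatheca list did not pass in 5 of 9 fits, with a camera adjusted p up to 0.112. Mitochondrial ribosomal proteins, cytosolic ribosomal proteins, glutathione S-transferases and respiratory chain genes had medians of 0.34, 0.20, 0.28 and 0.22. Without S106>UASfoxo control replicate 2 the respiratory chain median was 0.045, with a camera adjusted p of 0.813. Without S106 control replicate 5 the cytosolic ribosomal median was 0.059, with a camera adjusted p of 0.495. Mitochondrial ribosomal proteins kept passing, with a median of 0.148 without S106>UASfoxo control replicate 4. With all libraries in the fit these 9 lists passed camera with the preset correlation. With an estimated correlation each had a camera adjusted p = 0.974, and fry called 0 of the 39 lists. Of 100 splits of the libraries, 95 gave at least as many lists. Those splits ignore the library round, which was taken to pair these groups, and with the round as a block 12 lists passed camera. The log2 fold changes of this comparison followed exon length with a Spearman rho of −0.434 over 9739 genes, which are not independent replicates. foxo stood at −0.27 ± 0.33, Xbp1 at −1.14 ± 0.55, Thor at 0.31 ± 0.49 and InR at 0.77 ± 0.43.

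The S106>UASfoxo control libraries enter both this comparison and the switch comparison, with opposite signs. Over 9819 genes the differences of mean log2 CPM had a correlation of −0.796 and a covariance of −0.264. Simulated libraries with no effect gave −0.526 (range −0.556 to −0.493) and a covariance of −0.169 over 100 sets. The simulated genes were independent and the libraries unpaired, so this narrow range leaves out variation that genes or paired libraries share. Whether −0.796 exceeds what shared controls give therefore cannot be told from it. With the 4 control libraries split in pairs between the comparisons, the correlation ran from −0.494 to 0.096 over 6 splits.

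In the gut, the gene identifiers of the table did not go with its counts, so rows are described without names and no gene list was tested. Rows carrying identifiers of cytosolic ribosomal protein genes, which are abundant in every cell, had a median percentile of 57.5 by mean count over 75 rows, against 99.3 over 90 rows in the fat body table. Over 12011 shared identifiers the Spearman rho of the mean counts between the tables was 0.015. For this reason the difference of the S106>UASfoxo switch effect between the tissues was not tested.

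**Figure D4:**
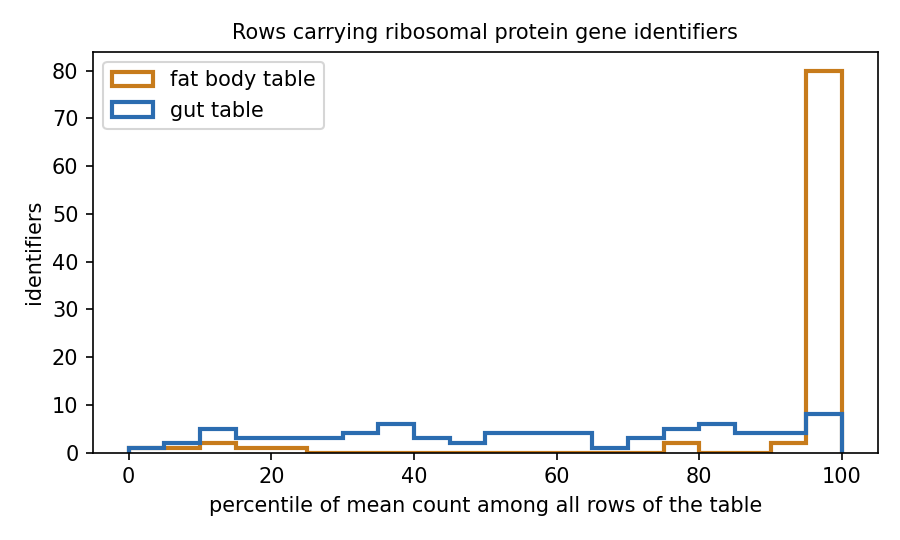
Percentile of the mean count, among all rows of the table, of rows that carry cytosolic ribosomal protein gene identifiers; lines count identifiers per bin. The median was 99.3 in the fat body table and 57.5 in the gut table.

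Between S106>UASfoxo switch and control in the gut, 1 of 9705 rows passed, and it was lower in the switch group with an edgeR adjusted p of 0.0141. DESeq2 called 7 rows and limma-voom 1. In simulated data they called 23 and 2 unchanged rows, and edgeR 4. DESeq2 there recovered 50.7, 82.1 and 93.9 percent of rows changed by log2 folds of 1, 2 and 3, and edgeR 43.3, 77.6 and 89.4. At an unadjusted p under 0.05 there were 577 rows, where chance gives 485. That number was 1730 without S106>UASfoxo switch replicate 2, 1030 without S106>UASfoxo control replicate 4 and 356 without S106>UASfoxo switch replicate 4. With the library round as a block, edgeR called 4 rows, with 963 rows at an unadjusted p under 0.05. The call ended when S106>UASfoxo control replicate 3 or S106>UASfoxo switch replicate 2, 3 or 4 was left out, each with 0 rows. Between S106 switch and control edgeR called 0 rows, limma-voom 0 and DESeq2 1, with 142 rows at an unadjusted p under 0.05. These became 341 without S106 control replicate 2, and 224, 82 and 79 without S106 switch replicates 1, 2 and 4. With title and round blocks they became 193 and 247. For the difference of the 2 switch effects all 3 tools called 0 rows, with 371 rows at an unadjusted p under 0.05. These became 184 and 573 without S106 control replicates 1 and 2, and 240 without S106 switch replicate 2. Without S106>UASfoxo control replicates 1, 2 and 4 they became 247, 233 and 609, and without S106>UASfoxo switch replicates 1 and 2 they became 240 and 1263. With title and round blocks they became 819 and 854, above the 485 of chance. Between S106>UASfoxo control and S106 control 2 rows passed, both higher in S106>UASfoxo, and 1 row with the replicate number as a block. DESeq2 called 12 rows and limma-voom 1, where in simulated data they called 35 and 11 unchanged rows and edgeR 12. DESeq2 there recovered 70.1, 92.5 and 98.5 percent of rows changed by log2 folds of 1, 2 and 3, and edgeR 61.2, 92.5 and 97. Leaving out any single library gave 0 or 1, and the 297 rows at an unadjusted p under 0.05, where chance gives 485, became 485 without S106>UASfoxo control replicate 1 and 205 without S106 control replicate 5. Over other splits the median numbers of rows at an unadjusted p under 0.05 were 435, 222, 312 and 277 for these comparisons in turn.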

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

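The tests of exon length, ovarian tissue, the S106>UASfoxo control group, library depth, library round, the gut identifiers, the splits that part paired libraries and the gene lists with each library left out were chosen only after the result was seen. The tests of S106>UASfoxo control replicate 4 and of other splits of the libraries were chosen before.

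The difference of the fat body switch effects, S106>UASfoxo minus S106, passed camera with the preset correlation for 16 gene lists, for 0 with an estimated correlation, for 11 with the round block and for 5 without S106 switch replicate 4. Cell cycle genes, neuron and enterocyte markers and both digestive lists were lost with the round block. Metabolic lists had median differences of 1.02 for glycolysis, 0.839 for gluconeogenesis and carbohydrate stores, 0.778 for lipid synthesis and 0.468 for lipid breakdown. Digestive carbohydrases and lipases had 1.699, digestive proteases 2.374 and enterocyte markers 2.374. The other marker lists had 0.522 for fat body, 1.026 for hemocytes, 0.546 for muscle, 0.57 for neurons, 0.477 for oenocytes and 1.256 for spermatheca. Cell cycle genes had −1.003, glutathione S-transferases −0.33 and mitochondrial ribosomal proteins −0.336. With an estimated correlation the adjusted p lay between 0.709 and 0.834, and 46 of 100 splits gave at least as many lists, up to 32, so chance cannot be excluded.

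Single libraries stood apart from their group in 8 of 84 sets of values, where chance gives about 4.2. In the gut, S106>UASfoxo switch replicate 3 had a total count, in units of 1e+06, of 4.51 against 7.33 to 7.86 in the others, and S106 control replicate 1 had 16.98 against 8.19 to 8.63. In the fat body, S106>UASfoxo switch replicate 4 had a mean log2 CPM of 7.43 for glycolysis against 8.34 to 8.51, and of 8.18 for gluconeogenesis against 9.17 to 9.22. Its log2 CPM of Xbp1 was 7.41 against 8.73 to 8.92, and of Argp 1.71 against 1.06 to 1.17. S106>UASfoxo control replicate 3 had 1.19 for digestive carbohydrases and lipases against 2.04 to 2.16. S106>UASfoxo switch replicate 1 had a log2 CPM of 3.62 for dpr9 against 2.56 to 2.71.

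Between S106>UASfoxo switch and control, 1269 fat body genes had an unadjusted p under 0.05, and 3 of 35 splits gave as many, up to 2097, so chance cannot be excluded. Ovarian tissue as the whole cause was argued against: with the ovary and egg mean as a covariate the number was 3197. Whether the S106>UASfoxo control libraries instead stood apart stays open. S106>UASfoxo switch against S106 switch gave 154 genes, where chance gives 491, and edgeR called 5 of the genes tested, 4 higher and 1 lower. Other splits in the fat body comparisons gave medians of 142 to 224, so a count of 154 cannot decide this. Transcript length or RNA quality and replicate 4 of S106>UASfoxo control cannot be told apart from an effect of the switch: removal of the length trend gave 1104 genes, and 573 to 1455 when a library was also left out, and leaving out replicate 4 alone gave 670. An effect of past dFOXO expression stays open.

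Ovary and egg transcripts spanned −1.31 to 6.58 log2 CPM over the 17 fat body libraries. Their means went with those of cell cycle genes at a Spearman rho of 0.9, and 0.811 within library rounds, so ovarian tissue carried along in some dissections is a candidate explanation. Library depth as the whole cause was argued against, because libraries of similar total count differed widely. S106>UASfoxo control replicate 2, with 11977047 counts, had −1.31, and S106>UASfoxo switch replicate 1, with 11833118, had 3.66. S106>UASfoxo switch replicate 3, with 9481397, had 1.21, and S106 switch replicate 4, with 9240567, had 6.58. Replicates 4 of S106>UASfoxo control and switch, with 6708078 and 6856804, were closer, at 4.14 and 5.32. A share for depth stays open. The rho with the total count was −0.52, with a permutation p of 0.03. Pearson's r was −0.439, with a permutation p of 0.07, and −0.429 without the 2 farthest libraries. Within rounds rho was −0.348 and r −0.423, with permutation p-values of 0.2 and 0.3. The library round cannot be told apart from chance: it held 51 percent of the variance, with a permutation p of 0.06. No biological explanation was tested, and egg production by the flies stays open.

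In the gut table, a true difference between the tissues was argued against by the median percentile of 57.5 for rows with cytosolic ribosomal protein identifiers, against 99.3 in the fat body. The rho of 0.015 between the mean counts of the tables over shared identifiers is consistent with identifiers that came apart from their counts. Where this happened is not given in the sources used here.

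Other splits of the libraries set a measure for each count of genes. Where the real count is 0, any split gives as many, so those counts of splits test nothing. This holds for the 35 splits of the fat body S106>UASfoxo switch comparison, with 0 genes called by edgeR (1269 at an unadjusted p under 0.05, and 53 called by DESeq2) and up to 221 in another split. For its 9 lists 31 of 35 splits gave as many, up to 29. For S106 switch against control in the fat body, with 0 genes called by edgeR, 68 at an unadjusted p under 0.05 and 1 called by DESeq2, it holds for the 100 splits, with up to 2427 called genes. For the 68 genes 74 splits did, up to 4440, and for its 10 lists 86, up to 32. For the difference in the fat body, with 0 called by edgeR and by DESeq2, it holds for the 100 splits too, with up to 1496, and for its 185 genes at an unadjusted p under 0.05 54 did, up to 3678. Chance cannot be excluded for the 68 and 185 genes or for the lists, and splits that call as many as 2427 genes point to a structure of the fat body samples.

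For the genotype difference in the fat body 3 of 100 splits gave as many as the 4 called genes, up to 3348, a share under 0.05 for splits that ignore the library round. Of the 16 splits that part the 4 pairs by round, too few for a share under 0.05, the highest other gave 0 genes in the same edgeR fit, and 0 with the round block, where the real split gave 2. For its 1083 genes at an unadjusted p under 0.05 13 splits gave as many, up to 4719, and for its 9 lists 95, up to 28. For the gut S106>UASfoxo switch comparison 6 of 100 splits gave at least the 1 called row, up to 867, but those splits ignore the pairing by round. The 16 splits that part its 4 pairs are too few for a share under 0.05: the highest other gave 0 rows by edgeR, and with the round block 1, where the real split gave 4. For its 577 rows at an unadjusted p under 0.05 32 of 100 splits gave as many, up to 3095. For S106 switch against control in the gut, with 0 rows called by edgeR and 1 by DESeq2, the 100 splits test nothing, with up to 1. For its 142 rows at an unadjusted p under 0.05 71 splits gave as many, up to 1420, without regard to the pairing by title number. For the gut difference, with 0 rows called by edgeR and by DESeq2, the 100 splits test nothing either, with up to 3, and for its 371 rows at an unadjusted p under 0.05 42 did, up to 1809. Those splits ignore the pairing, and with title and round blocks the 371 became 819 and 854. For the gut genotype difference 1 of 100 splits, the real one, gave the 2 called rows, with up to 1 in the others, but those splits ignore the pairing by title number. The 16 splits that part the 4 pairs are too few for a share under 0.05: the highest other gave 0 rows, and with the title replicate block 1, as the real split did. For its 297 rows at an unadjusted p under 0.05 44 of 100 splits gave as many, up to 1291, and the 297 became 485, the number of chance, without S106>UASfoxo control replicate 1.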

How the results depend on the processing

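The fits with 2 and 3 surrogate variables, with list means as covariates, with the exon length trend removed, without libraries high in ovarian transcripts, and camera with the round block and with each library left out were chosen only after the result was seen; the others were planned. Of the counts under alternatives other than left-out libraries, 82 stayed within 1.5 times and 52 moved. Most of the 82 were counts of 0 that stayed at 0, which says little on robustness. The results of single named genes were tallied once per gene, comparison and alternative fit, so they are not numbers of genes. Under the same alternatives 1387 such results kept their direction and side of the threshold and 83 passed only in the alternative. A further 16 no longer passed and 20 changed direction. With each library left out, 874 kept both, 35 no longer passed and 22 changed direction. The cause was not tested where none is given. In the simulated fat body data of the S106>UASfoxo switch comparison, 13.4 percent of genes changed by a log2 fold of 1 were recovered at this depth and spread. The planned test of the difference between tissues was not run because the gut identifiers did not go with the counts.

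For the fat body S106>UASfoxo switch comparison edgeR called 0 genes (1269 at an unadjusted p under 0.05). With title and round blocks it also called 0, with 1805 and 1790 at an unadjusted p under 0.05. DESeq2 called 53, and edgeR 1 with 1 surrogate variable, 423 with 2 and 520 with 3. It called 1480 with the ovary and egg mean, 1 with the cell cycle mean and 1672 with both means. Without the libraries whose ovary and egg mean was above 3 it called 0, with 1513 at an unadjusted p under 0.05. That fit kept 9 libraries, with 2 of S106>UASfoxo control and 2 of S106>UASfoxo switch, so its 0 says little on ovarian content. For S106 switch against control edgeR called 0 genes (68 at an unadjusted p under 0.05) and DESeq2 1. For the difference every alternative, DESeq2 and limma-voom included, called 0 (185 at an unadjusted p under 0.05 by edgeR). Leaving out each library gave 0 called genes in these 3 comparisons, and for the S106>UASfoxo switch comparison 670 to 1716 genes at an unadjusted p under 0.05, for S106 switch against control 28 to 185 and for the difference 81 to 553.

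For the genotype difference in the fat body, 4 genes in the planned fit, the count was 18 with DESeq2, 2 with limma-voom, 1 with the title replicate block, 2 with the round block, 10 with 1 surrogate variable, 366 with 2 and 5 with 3. It was 10 with the ovary and egg mean, 7 with the cell cycle mean, 9 with both means and 9 with the cell cycle mean and round block. It was 0 at a threshold of 0.01, 0 with only the groups compared in the fit and 0 to 1 with each library left out. It was also 0 without the libraries high in ovarian transcripts, where only 2 S106>UASfoxo control and 3 S106 control libraries remained. At an unadjusted p under 0.05 there were 1083 genes in the planned edgeR fit, and 1667 and 1650 with title and round blocks. There were 1408 without the libraries high in ovarian transcripts, and 493 to 1393 with each library left out, the 493 without S106>UASfoxo control replicate 4.

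In the gut S106>UASfoxo switch comparison, 1 row in the planned fit, the count was 7 with DESeq2, 4 with the round block, 2 with 2 and 2 with 3 surrogate variables, 0 at a threshold of 0.01 and 0 with only the groups compared (577 at an unadjusted p under 0.05 by edgeR). It was 0 to 2 with each library left out, with 2 without S106>UASfoxo control replicate 4, and 356 to 1730 rows at an unadjusted p under 0.05. For S106 switch against control in the gut, 0 in the planned edgeR fit (142 at an unadjusted p under 0.05), the count was 1 with DESeq2, 1 with the round block, 1 with 1 surrogate variable, 0 with 2 and 3, and 0 with each library left out. For the gut difference it was 0 in every alternative, DESeq2 and limma-voom included (371 at an unadjusted p under 0.05 by edgeR). With title and round blocks the 371 became 819 and 854. For the gut genotype difference, 2 in the planned fit, it was 12 with DESeq2, 1 with limma-voom, 1 with the title replicate block, 5 with the round block, 1 with each of 1, 2 and 3 surrogate variables, 0 at a threshold of 0.01, 0 with only the groups compared (297 at an unadjusted p under 0.05 by edgeR) and 0 to 1 with each library left out, with 205 to 485.

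With an estimated correlation camera passed 0 lists in each fat body comparison, and fry 0. The title replicate block gave 17 lists for S106 switch against control, 25 for the difference and 14 for the genotype difference, against 10, 16 and 9. Where title numbers paired the gut libraries, that block took the genotype difference from 2 called rows to 1 and left S106 switch against control at 0. The round block gave 11 lists for the difference and 12 for the genotype difference, 14 for the S106>UASfoxo switch comparison and 19 for S106 switch against control. Under it both digestive lists no longer passed in the S106>UASfoxo switch comparison and the difference, nor digestive proteases in the genotype difference. Neuron markers no longer passed in S106 switch against control and the difference, nor cell cycle genes and enterocyte markers in the difference. With each library left out 7 to 14 lists passed in the S106>UASfoxo switch comparison, 4 to 19 in S106 switch against control, 5 to 23 in the difference and 7 to 13 in the genotype difference.

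The direction of some single genes turned. Thor in the S106>UASfoxo switch comparison had 0.105 with the ovary and egg mean, 0.006 with both means, 0.186 with the length trend removed, 0.281 without libraries high in ovarian transcripts, and −0.235 to 0.182 with each library left out, and InR −0.709 to 0.078. In S106 switch against control, foxo had 0.029 with 3 surrogate variables, 0.072 with the ovary and egg mean, 0.002 with the cell cycle mean, 0.068 with both, and −0.228 to 0.127 with each library left out. Xbp1 had −0.271 with the title replicate block, −0.125 with the round block, and −0.229 to 0.326. Thor had 0.01 with the cell cycle mean, 0.015 without libraries high in ovarian transcripts, and −0.534 to 0.052, and Cp38 −0.93 to 8.389. For the difference, Thor had −0.007 with the round block, −0.102, −0.059 and −0.023 with 1, 2 and 3 surrogate variables, −0.108 with the cell cycle mean, −0.153 with that mean and the round block, and −0.061 to 0.525. InR had −0.155 with the length trend removed and −0.189 to 0.599. Thor in the genotype difference had −0.021 without libraries high in ovarian transcripts.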

Other observations

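The covariate fit, the mean genotype contrast and the test of called genes on 3R were chosen only after the result was seen; the test of genes not called on 3R was chosen before.

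With the ovary and egg mean as a covariate, the fat body S106>UASfoxo switch comparison had 11 of 14 glycolysis genes called higher by edgeR, with a median log2 fold change of 1.42, and 6 of 11 gluconeogenesis genes, with 1.04. Of the lipid synthesis genes 10 of 22 were called higher, of lipid breakdown 7 of 16 and of hemocyte markers 7 of 15, while 11 of 72 mitochondrial ribosomal protein genes were called lower. At an estimated correlation none of these lists passed camera in this fit. Glycolysis, gluconeogenesis and hemocyte markers had an adjusted p of 0.560, both lipid lists 0.799 and mitochondrial ribosomal proteins 0.8255. The fit called 1480 genes, and 1 of 35 splits, the real one, gave as many, with up to 818 in the others. It was chosen among several covariate fits, and the cell cycle mean in its place gave 1 gene, so a switch effect that ovarian content may hide is only a hypothesis. With this covariate the difference of the 2 switch effects called 0 genes by edgeR, with 927 at an unadjusted p under 0.05, and without it edgeR and DESeq2 called 0, with 185.

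The mean of both S106>UASfoxo groups against the mean of both S106 groups in the fat body called 7 genes by edgeR, 5 higher and 2 lower. Besides dpr9, Dop1R1, Argp and CG43064 these were Egfrap at a log2 fold change of 6.14 ± 0.61, CG34301 at 4.33 ± 0.66 and lncRNA:dntRL at −2.44 ± 0.42. dpr9, Dop1R1 and Argp lie within 1.5 megabases of foxo on 3R, as do 265 of 9739 tested genes, with a one-sided Fisher's exact p of 0.000643. A sequence linked to 1 site on 3R in the S106>UASfoxo flies, a difference of genetic background or insertion, is a candidate explanation found on the same data. Genes near foxo that were not called showed no excess: 17 of 262 had an unadjusted p under 0.05, 6.5 percent against 8.2 percent elsewhere, with a one-sided Fisher's exact p of 0.869.

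In the gut the same mean contrast called 68 rows by edgeR, 57 higher and 11 lower in S106>UASfoxo, and S106>UASfoxo switch against S106 switch called 10.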
